A study of Homo sapiens with 14 samples.

How the data were processed

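RNA-seq was done on 12 libraries of U251MG cells, 3 each of control cells, radioresistant cells, radioresistant cells with the hairpin shNC and radioresistant cells with shIFI16, and ATAC-seq on 1 control and 1 radioresistant library. Per the labels, the cells were grown in DMEM with fetal bovine serum, RNA was extracted with Trizol, and RNA libraries were made with the NEBNext Ultra mRNA kit. Per the labels, open chromatin was tagged with Tn5 and the Nextera kit after a protocol of Active Motif. Groups of the samples were taken from the labels, and replicates were numbered as the labels number them. Columns of RNA values carry codes only, and their groups were inferred. UN was read as control and UR as radioresistant by the prefixes of the ATAC-seq pair, and URS as shIFI16 because URN was read as shNC. Low IFI16 in the URS columns went with this reading, but control and radioresistant columns have no such check. Both RNA tables were named as counts, but the deposited values were TPM, as each column summed to 1000000 and the values were not whole numbers. The submitters' processing notes list Trim Galore 0.6.6, TopHat, Cufflinks 2.2.1 and featureCounts for the RNA libraries and the build hg38; which of them made the deposited TPM, the annotation and the use of strand are not given in the sources used here. For the ATAC-seq libraries the notes list the same tools and also Bowtie2 2.2.5, SAMtools 1.10 and MACS2 2.1.4. The authors deposited 1 list of MACS2 summits per library, with a -log10 q-value as the score of each summit by the layout of the file; the settings of the peak caller are not given in the sources used here.

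TPM keeps no sequencing depth, so no interval from counting could be given for expression, and the planned count-based tests were replaced by limma 3.58.1 in R 4.3.3 on log2(TPM + 1). Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. Genes with at least 1 TPM in at least 3 of the 6 libraries of a comparison were tested, 28 entries whose names had become dates were left out (0.115 to 0.190% of the values of a library), and each comparison was fitted within its own table. The filter still asked for 3 libraries when 1 was left out. Genes at 1 TPM or more only in the group that lost a library then went untested. A gene under 1 TPM in a whole group can pass only through the other group, which sets the direction of its change. Variances were moderated with a trend and robustly, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 2 tables were normalized separately, so no gene or list was tested across them. Small RNA took 0.168 to 0.423% of the values in the first table and 1.30 to 3.10% in the second, and the 10 highest genes took 6.59 to 8.31%. Values of gene families with close copies or pseudogenes (HLA, IFITM, OAS, AKR1C, histones, KRT8, FTH1, MAGEA12 and ribosomal proteins) and of overlapping or antisense genes are uncertain.

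The comparisons, gene lists, rule for named genes and the alternatives of replicate block, left-out libraries, list tests, set limits and most ATAC-seq distances and scores were fixed before the data were examined. The rule named IFI16 and HMOX1, and in each comparison the 10 largest rises and 10 largest falls among genes past the threshold, at least 2-fold changed, with a mean of at least 2 (planned in CPM, applied to TPM) and no overlap between groups. It also named up to 4 members per list by smallest p, members needed to say what did not change, and 5 genes per opposite direction for the overlap. Outside the rule, and chosen after their values were seen, were IFI6, XAF1, HLA-F, B2M, STING1, TXNRD1, SQSTM1, GPX4, ALAS1, SOX2, GJA1, IGFBP3 and CDKN1A in radioresistant cells, CXCL10, MX1, STC1, CXCL8, CEBPD, EGR1, GPX4, ACSL4 and TFRC after knockdown, and IFITM2. Some members of the lists are not reported here by name. The 29 lists covered interferon-stimulated genes, nucleic acid sensing, antigen presentation, secreted senescence factors, cell-cycle inhibitors, proliferation, DNA break repair, p53 targets, ferroptosis suppressors and drivers, NRF2 targets, heme and iron, NF-kB targets, mesenchymal and proneural glioblastoma genes, extracellular matrix, cholesterol synthesis, hypoxia and glycolysis, stress responses, immediate early genes, mitochondrially encoded genes, ribosomal proteins, replication histones, and markers of immune, endothelial, epithelial, neuron, oligodendrocyte and astrocyte cells. Lists with at least 5 tested members were compared with other genes by camera with a preset correlation of 0.01, two-sided, beside camera with an estimated correlation and fry. With 6 libraries the estimated form gave larger p-values even where the estimated correlation lay under 0.01. For NRF2 targets in radioresistant cells that correlation was -0.0041, and camera's unadjusted p went from 3.3e-07 to 0.0045. A list that missed the threshold in that form is thus not shown to have passed through correlation between genes. Overlap of calls was tested by Fisher's exact test across genes.

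ATAC-seq summits of the 2 lists were called shared within 250 bp, and genes were matched by symbol to a RefSeq gene table of the same build, which placed 12069 of 13127 tested genes (91.9%). That table gave no strand, so distance was measured to either gene end, with 1 kb as the limit, and coordinates are 1-based. Shares have exact 95% Clopper-Pearson intervals, which cover counting error only.

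The fits were tested on simulated data with 200 changed genes. For radioresistant against control (13127 genes simulated) 35.8%, 74.6% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold were found, and 7 of 143 calls were wrong. For shIFI16 against shNC (12567 genes simulated) 67.2%, 95.5% and 98.5% were found, and 4 of 178 calls were wrong. Of 20 unchanged lists 0 passed in either, but the simulated genes were drawn independently of each other. The simulation therefore cannot show how often lists of correlated genes pass wrongly. Alternatives covered pseudocounts of 0.1 and 0.5 TPM, no filter, a filter at 2 TPM, median-ratio scaling, quantile normalization, small RNA left out, limma without trend and robust fitting, a 2-fold limit in the test, a replicate block, each library left out, the list tests, the set limits and the ATAC-seq distances and scores. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used for ATAC-seq, tables and plots.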

Results

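Gene expression was measured by RNA-seq in 12 libraries of U251MG, an established human glioblastoma cell line, and open chromatin was measured by ATAC-seq in 2 further libraries of the same line. Control cells stood beside radioresistant cells, which had received X-rays in 30 fractions of 2 Gy each, 60 Gy in sum. Radioresistant cells also carried a short hairpin RNA against IFI16 (shIFI16) or a hairpin labelled shNC, the comparison group of the knockdown. The labels name no second hairpin against IFI16 and no rescue. Effects of IFI16 loss therefore cannot be told apart from off-target effects or from other differences between the hairpin populations. Each of the 4 RNA groups held 3 libraries and each ATAC-seq condition held 1. Expression was given in TPM (transcripts per 1000000), and the values of every library summed to 1000000, so the sequencing depth behind them is unknown. Between 12380 genes (shNC replicate 2) and 13036 genes (control replicate 2) reached 1 TPM in a library. Across genes, which are not independent replicates, Pearson's r of log2 TPM was 0.975 to 0.993 between control libraries, 0.990 to 0.992 between radioresistant libraries, 0.992 to 0.993 between shNC libraries and 0.990 to 0.992 between shIFI16 libraries. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

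The series asked what IFI16 does in radioresistant glioblastoma cells, and its title also names HMOX1, senescence and ferroptosis. IFI16, a sensor of foreign and damaged DNA (chromosome 1, 158999976 to 159055151, hg38), stood at 70.3, 71.1 and 49.6 TPM in the control libraries and at 250.8, 309 and 243 TPM in the radioresistant libraries. In the knockdown set, IFI16 stood at 125, 140 and 127 TPM in the shNC libraries and at 7.68, 7.90 and 6.71 TPM in the shIFI16 libraries, which went with the labels in every library. HMOX1, which encodes the enzyme that breaks down heme and releases iron (chromosome 22, 35381096 to 35394207, hg38), stood at 19.7, 25 and 26.4 TPM in control, 178, 168 and 260 TPM in radioresistant, 32.1, 34.8 and 30.1 TPM in shNC and 21.2, 23.6 and 21.5 TPM in shIFI16 libraries. The control and radioresistant libraries came from one table and the hairpin libraries from another, and changes of genes and lists were tested only within a table.

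**Figure D1:**
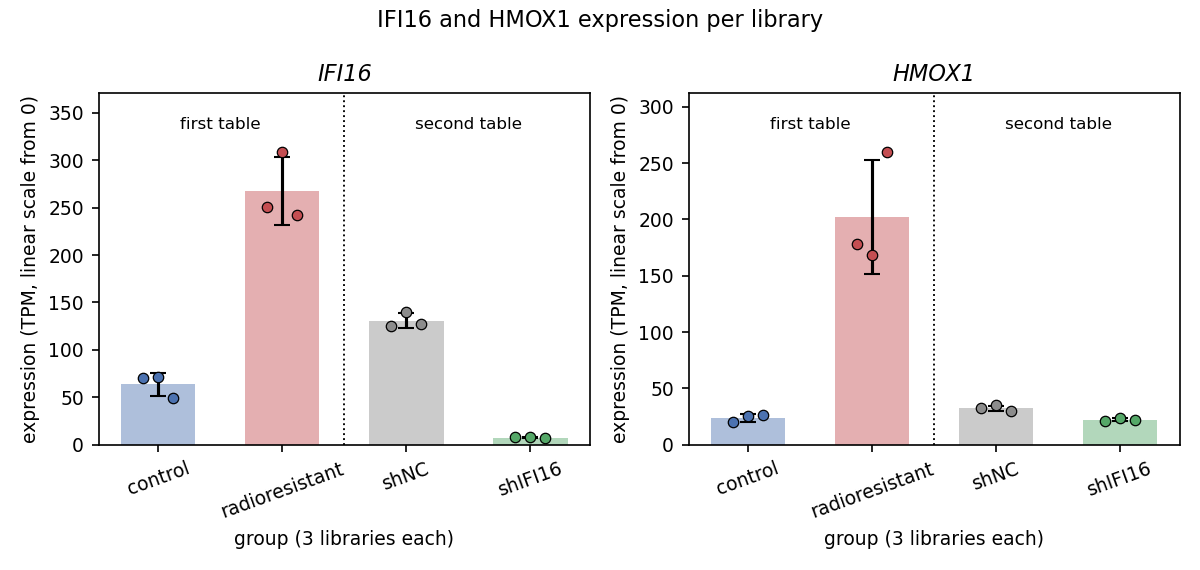
Expression of IFI16 (left) and HMOX1 (right) in TPM on a linear axis that starts at 0, for the 4 RNA groups. Bars show the mean of 3 libraries, error bars the SD, and points the single libraries; the dotted line parts the 2 tables. Mean IFI16 was 63.7 TPM in control, 267 TPM in radioresistant, 131 TPM in shNC and 7.43 TPM in shIFI16 libraries.

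In radioresistant cells 39 of 39 tested interferon-stimulated genes and 14 of 18 antigen-presentation genes rose against control cells and 0 fell, while 5 of 5 astrocyte markers and 8 of 11 proneural and stem genes fell and 0 and 1 rose. With an estimated correlation these 4 lists had an adjusted p = 0.13, 0.17, 0.13 and 0.17, none past the threshold. IFI16 rose by 2.06 (log2, SE 0.156, limma adjusted p = 3.8e-06), from 63.7 ± 12.2 TPM in control to 267 ± 36.1 TPM in radioresistant cells (mean ± SD, n = 3 each). HMOX1 rose by 3.02 (log2, SE 0.175, adjusted p = 5.0e-07), from 23.7 ± 3.53 to 202 ± 50.4 TPM. The astrocyte filament gene GFAP fell by 5.66 (log2, SE 0.181, adjusted p = 9.9e-09), from 4011 ± 112 to 80.6 ± 22.9 TPM.

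Of the 10 genes with the largest rises, 8 were members of the interferon list fixed in advance and HLA-B was a member of the antigen-presentation list. LY6E, a membrane-anchored protein (chromosome 8, 143018529 to 143022409, hg38), rose by 6.85 (log2, SE 0.137, adjusted p = 1.0e-09), from 17.3 ± 2.45 to 2117 ± 302 TPM. RSAD2, which encodes the antiviral enzyme viperin, rose by 6.63 from 0.192 ± 0.0954 to 117 ± 14.9 TPM. The OAS genes make the 2-5A messenger that activates RNase L: OAS2 rose by 6.48 from 3.40 ± 1.66 to 373 ± 51.4 TPM and OAS1 by 5.99 from 4.95 ± 1.61 to 368 ± 28.6 TPM. HLA-B, a class I antigen-presenting molecule, rose by 6.34 to 818 ± 205 TPM, and the immunoproteasome subunit PSMB9 rose by 6.16 to 185 ± 53.8 TPM. The nucleotide kinase gene CMPK2 rose by 6.25. Its span on chromosome 2 (6840553 to 6866635) overlaps that of RSAD2 (6865885 to 6898239). As the use of strand is not given, reads may not have been told apart in the shared stretch. The dynamin-like antiviral GTPase genes MX2 and MX1 rose by 5.73 and 5.46, and IFITM1, which blocks viral entry, rose by 5.21 from 97.2 ± 11.2 to 3660 ± 622 TPM. Largest adjusted p among these 10 was 4.8e-07 (OAS2).

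After GFAP, the largest falls under the rule for named genes were found in a further 9 genes. The transcription factor gene ZNF423 fell by 5.45 from 53.9 ± 4.41 to 0.25 ± 0.0496 TPM. GPM6B, a membrane glycoprotein of the nervous system, fell by 5.21 from 322 ± 49.3 to 7.70 ± 0.743 TPM. The collagen gene COL21A1 (-4.87), the secreted protein gene SCUBE3 (-4.85) and the cannabinoid receptor gene CNR1 (-4.81) also fell. IGFBP5, which binds insulin-like growth factors, fell by 4.71 from 189 ± 13 to 6.57 ± 2.47 TPM. The neuropeptide Y receptor gene NPY1R fell by 4.49 and FAIM2, an inhibitor of FAS-driven cell death, fell by 4.04. KLHDC8A averaged 15.2 ± 1.93 TPM in control cells and was listed at 0 in all 3 radioresistant libraries (adjusted p = 2.3e-08). For the other genes named in these falls, GFAP aside, the adjusted p lay between 2.0e-09 and 1.7e-07.

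Of the 29 gene lists fixed in advance, 23 had at least 5 tested members here, and 14 passed camera's test with a preset correlation of 0.01. The interferon list had a median of 3.36 (adjusted p = 5.1e-37), with 39 of 39 tested members raised, and 39 adjusted over the list alone. Its adjusted p = 0.13 with an estimated correlation. The list held 43 genes, and CXCL10, CXCL11, IRF7 and EPSTI1 were too low to test. On means under 1 TPM EPSTI1 went down (0.534 to 0.0207 TPM) and the others up. RSAD2, CMPK2, MX2 and XAF1 lay under 1 TPM in all control libraries and passed the filter through the radioresistant ones. The filter thus set their direction. ISG15, a ubiquitin-like modifier, rose by 4.94 to 7341 ± 799 TPM, and IFI6, a survival factor of the mitochondrion, rose by 4.70 to 9864 ± 1788 TPM. In the antigen-presentation list 14 of 18 tested members rose and 0 fell, and 15 rose adjusted over the list alone (median 2.28, adjusted p = 1.2e-11, or 0.17 with an estimated correlation). The peptide transporter gene TAP1 rose by 4.36, HLA-F by 4.61, the immunoproteasome gene PSMB8 by 2.75 and B2M, the class I light chain, by 2.13 to 5112 ± 886 TPM. In the nucleic-acid-sensing list, of which IFI16 is itself a member, 9 of 16 rose and 3 fell, with 9 and 4 adjusted over the list alone (median 0.50, adjusted p = 9.9e-04; adjusted p = 0.17 with an estimated correlation). The RNA sensor genes IFIH1 and DDX58 (RIG-I) rose by 2.80 and 2.48, and the dNTP hydrolase gene SAMHD1 by 2.25, while STING1, the adaptor below cGAS, listed as TMEM173, fell by 0.73 (adjusted p = 0.0047).

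Of 29 tested NRF2 targets, genes of the oxidative stress response, 16 rose and 2 fell, with 17 and 2 adjusted over the list alone (median 0.48, adjusted p = 1.9e-06; adjusted p = 0.10 with an estimated correlation). Beside HMOX1, the aldo-keto reductase genes AKR1C1 and AKR1B10 rose by 2.56 and 1.72 and thioredoxin reductase TXNRD1 by 1.18. Among 21 NF-kB targets 12 rose and 2 fell, with 12 and 2 adjusted over the list alone (adjusted p = 1.5e-04; adjusted p = 0.12 with an estimated correlation). The chemokine gene CCL5 rose by 2.45, the adhesion molecule gene ICAM1 by 1.40 and the transcription factor gene IRF1 by 1.23, while the chemokine gene CCL2 fell by 1.41. CCL5 averaged 0.130 ± 0.159 TPM in control cells and passed the filter through the radioresistant libraries, which set its direction. Immediate early genes rose in 13 of 17 cases with 0 falls, and in 14 adjusted over the list alone (median 0.76, adjusted p = 5.6e-07; adjusted p = 0.17 with an estimated correlation). Among them KLF4 rose by 1.80, MYC by 1.64 and EGR1 by 1.45, all of which encode transcription factors. Replication histones rose in 7 of 19 cases with 0 falls, and in 5 adjusted over the list alone (adjusted p = 7.7e-04; adjusted p = 0.13 with an estimated correlation); HIST1H2AC rose by 1.47 and HIST1H1C by 0.82, and near-identical copies make such values uncertain. Among 25 genes of the unfolded-protein and integrated stress responses 12 rose and 5 fell, with 12 and 5 adjusted over the list alone (adjusted p = 0.024; adjusted p = 0.17 with an estimated correlation). There TRIB3 rose by 1.40 and ATF4, its upstream transcription factor, by 1.00, and the serine synthesis gene PHGDH fell by 1.16. That call ended with quantile normalization, where its adjusted p was 0.069, within a range of 0.013 to 0.069 over the alternatives. Its median of 0.21 moved to 0.09 without control replicate 1 and to 0.33 without control replicate 3.

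Genes that guard against ferroptosis, iron-driven death by lipid peroxidation, moved both ways. Among 28 tested suppressors 12 rose and 7 fell, with 13 and 7 adjusted over the list alone (median 0.34, adjusted p = 0.028; adjusted p = 0.17 with an estimated correlation). HMOX1 had the largest rise of the list and the autophagy receptor SQSTM1 rose by 1.01, whereas the desaturase genes SCD and FADS2 fell (-2.61 and -2.25). GPX4, which reduces lipid peroxides, fell by 0.98 (adjusted p = 1.3e-04), from 983 ± 115 to 497 ± 48.1 TPM. SLC7A11, the cystine transporter, did not pass (log2 change 0.11, adjusted p = 0.55). FTH1, the ferritin heavy chain, stood at 335, 541 and 1703 TPM in control replicates 1, 2 and 3 against 2241 ± 139 TPM in radioresistant cells (log2 change 1.73, SE 0.641, adjusted p = 0.089). Without control replicate 3 the adjusted p of FTH1 was 1.6e-06, within a range of 1.6e-06 to 0.25 over the alternatives. The suppressor list did not pass without a low-value filter (adjusted p = 0.086), with median-ratio scaling (0.076), with quantile normalization (0.069) or without control replicate 3 (0.058), within a range of 0.021 to 0.086. Drivers of ferroptosis did not pass, with 4 of 24 raised and 8 lowered, and 4 and 8 adjusted over the list alone (adjusted p = 0.27). The directional test fry, which asks whether a list moves one way and not whether it differs from other genes, gave the drivers an adjusted p = 0.0064 downward. The polyamine enzyme gene SAT1 fell by 1.27 among them, and ACSL4, which loads the oxidizable lipids, had a log2 change of -0.27 (adjusted p = 0.17). That change of ACSL4 was -0.42 without control replicate 3 (adjusted p = 0.0047) and -0.16 without control replicate 1 (adjusted p = 0.44, range 0.0047 to 0.44). For heme and iron genes 10 of 28 rose and 4 fell, with 10 and 4 adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.15 with an estimated correlation). HEPH, a ferroxidase of iron export, rose by 3.44 and the heme synthesis gene ALAS1 by 0.84, and the iron regulatory protein gene ACO1 fell by 1.83.

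All 5 tested astrocyte markers fell in radioresistant cells, and 5 adjusted over the list alone (median -2.45, adjusted p = 1.5e-04; adjusted p = 0.13 with an estimated correlation). Beside GFAP these were the fatty acid binding gene FABP7 (-2.45), S100B (-2.79), the glutamate transporter gene SLC1A3 (-1.11) and the gap junction gene GJA1 (-0.96). Of 11 proneural and stem genes 8 fell and 1 rose, with 8 and 1 adjusted over the list alone (median -1.31, adjusted p = 0.0020; adjusted p = 0.17 with an estimated correlation). The receptor tyrosine kinase gene PDGFRA (-3.18) and the RNA-binding protein gene MSI1 (-2.79) fell, and the stem cell factor SOX2 fell by 1.48 from 420 ± 75.2 to 149 ± 20.5 TPM. Without a low-value filter this list did not pass (adjusted p = 0.22, range 0.0011 to 0.22 over the alternatives), and its median was -0.83 without control replicate 2 and -0.79 without control replicate 3. Of 23 cholesterol synthesis genes 13 fell and 2 rose, with 14 and 2 adjusted over the list alone (median -0.49, adjusted p = 0.014; adjusted p = 0.17 with an estimated correlation), among them INSIG1 (-1.35) and LSS (-1.10). Of 47 proliferation genes 12 rose and 3 fell, with 10 and 3 adjusted over the list alone (median 0.14, adjusted p = 0.014; adjusted p = 0.60 with an estimated correlation). The replication licensing genes CDT1 and MCM5 rose by 1.14 and 0.58 and the checkpoint kinase gene BUB1B fell by 0.73. Without control replicate 3 the proliferation list did not pass (median 0.09, adjusted p = 0.10, range 0.0011 to 0.10), nor did it by fry (adjusted p = 0.20).

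The lists most tied to senescence did not pass camera's test. By fry, secreted senescence factors passed downward (adjusted p = 0.0042), p53 targets upward (adjusted p = 0.012) and mesenchymal genes upward (adjusted p = 0.021). Of 33 secreted senescence factors 12 rose and 12 fell, with 13 and 15 adjusted over the list alone (median 0.06, mean -0.21, adjusted p = 0.87); IGFBP3 rose by 1.97, while the protease genes PLAU (-2.77) and MMP2 (-1.92) and IGFBP4 (-2.85) fell. Of 10 cell-cycle inhibitors 4 rose and 4 fell, the same numbers as adjusted over the list alone (median -0.11, mean 0.03, adjusted p = 0.68). CDKN1A, which encodes p21, rose by 0.62 (adjusted p = 0.014), but not without radioresistant replicate 1 (0.057, range 0.0060 to 0.057), and GADD45A rose by 1.89 while BTG2 fell by 1.69. Of 29 p53 targets 10 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.082), with the kinase gene PLK2 up by 1.60. DNA break repair genes rose in 6 and fell in 5 of 37 cases, and in 5 and 5 adjusted over the list alone (adjusted p = 0.52). Their median was -0.02 as deposited and turned to 0.10 with median-ratio scaling and 0.05 with quantile normalization; TP53BP1 fell by 0.75 and XRCC3 rose by 0.90. Neither did mesenchymal glioblastoma genes (9 raised and 10 lowered of 27, 9 and 11 adjusted over the list alone, adjusted p = 0.30) nor extracellular matrix genes (10 and 9 of 31, also adjusted over the list alone, adjusted p = 0.58, median 0.01, mean -0.03) pass. The matrix protein gene THBS1, a member of both, rose by 2.14, the cross-linking enzyme gene LOXL1 fell by 3.15, and CHI3L1 was listed at 0 in all 3 control libraries and averaged 8.35 ± 3.40 TPM in radioresistant ones. Hypoxia and glycolysis genes rose in 4 and fell in 8 of 24 cases, and in 5 and 8 adjusted over the list alone (adjusted p = 0.60), with BNIP3L at -1.51 and LDHA at -0.86. Ribosomal protein genes rose in 2 and fell in 18 of 76 cases, and in 2 and 11 adjusted over the list alone (adjusted p = 0.60).

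Markers of other cell types were mostly below the level needed for testing. Only 1 immune marker (CD68, log2 change 0.22, adjusted p = 0.26), 2 endothelial, 2 epithelial, 4 neuron and 1 oligodendrocyte marker were tested. Without control replicate 1 the change of CD68 was 0.11 (adjusted p = 0.64). The endothelial cadherin gene CDH5 (-2.37), the epithelial factor gene ELF3 (-0.92), the neurofilament gene NEFL (-2.60) and the synaptic gene SYT1 (-0.89) fell, while 0 of these markers rose over all genes. The list of 13 mitochondrially encoded genes was not analysed here, with 0 genes tested in either comparison. Adjusted over the list alone, 2 endothelial, 1 epithelial and 2 neuron markers fell and 1 oligodendrocyte marker rose.

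By limma with Benjamini-Hochberg adjustment, 5762 of 13127 tested genes changed at adjusted p 0.05, 2220 up and 3542 down, and 6846 had an unadjusted p under 0.05. At least 2-fold changes were found in 651 raised and 839 lowered genes. The 3 radioresistant values lay wholly above or below the 3 control values in 6973 genes (53.1%), where chance gives 10%. The median gene lay at -0.11 (log2) in TPM as deposited and at 0.003 after median-ratio scaling, so fold changes relative to the median gene are 0.11 higher than those given. Median-ratio scaling gave 2943 raised and 2974 lowered genes, which moved the raised share of all calls from 38.5% to 49.7%. Leaving out control replicate 2 gave 2237 lowered genes in place of 3542.

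**Figure D2:**
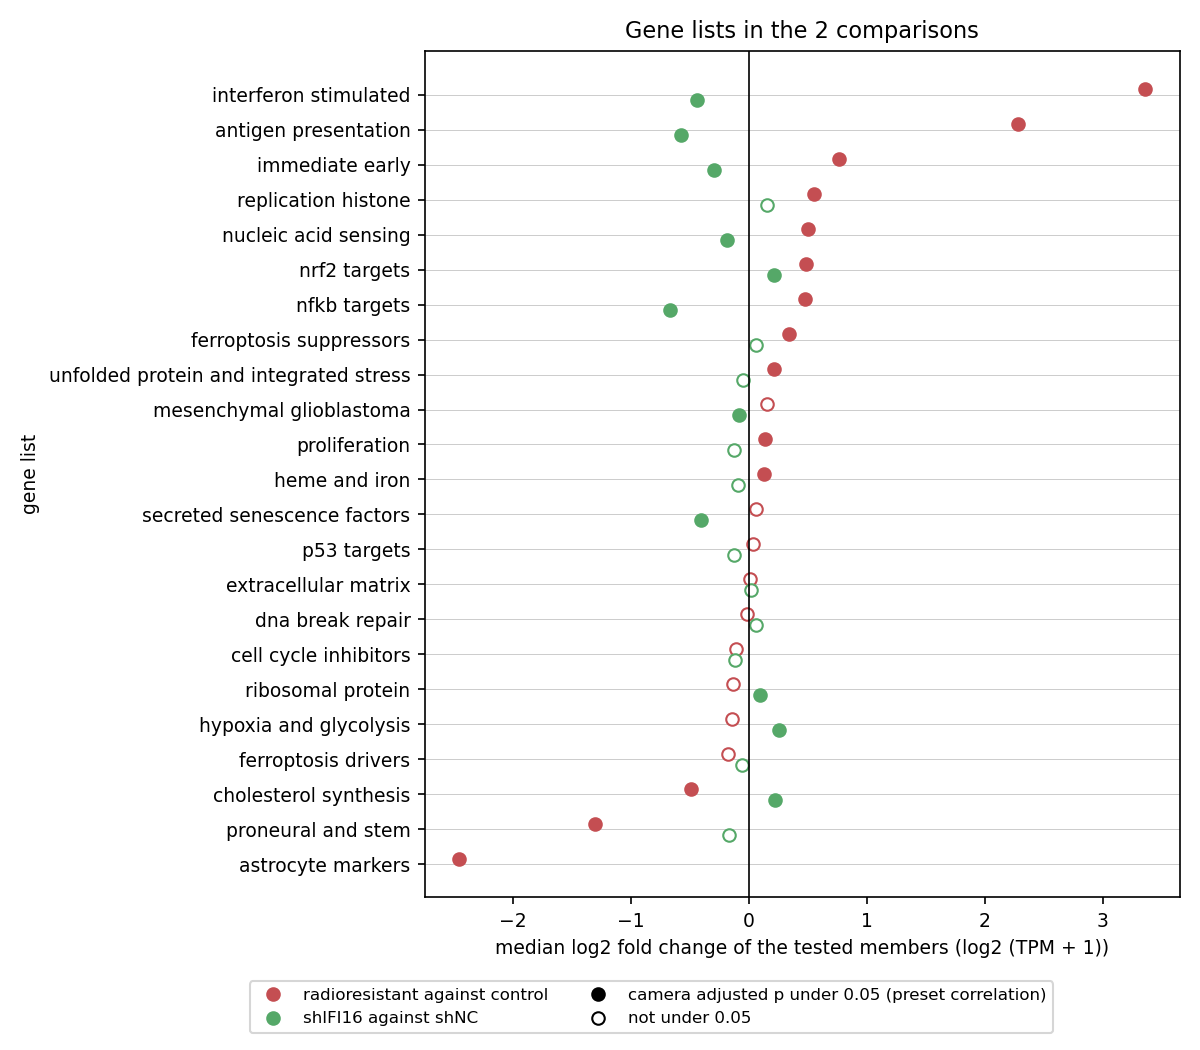
Median log2 fold change (log2 of TPM + 1) of the tested members of each gene list, in radioresistant against control cells (red) and in shIFI16 against shNC cells (green). Filled points passed camera's test at an adjusted p of 0.05 with the preset correlation and open points did not. No list passed with an estimated correlation, a form that gave larger p-values even where that correlation lay under 0.01. The interferon list lies at 3.36 in the first comparison and at -0.44 in the second, and with another scaling the medians of DNA break repair in the first and of extracellular matrix in the second turned sign.

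After knockdown of IFI16 in radioresistant cells, 25 of 40 interferon, 13 of 18 antigen-presentation and 14 of 21 NF-kB target genes fell, while 5, 1 and 4 rose, and GFAP rose. With an estimated correlation these lists did not pass (adjusted p = 0.20, 0.20 and 0.16). IFI16 fell by 3.97 (log2, SE 0.0883, limma adjusted p = 4.4e-14), from 131 ± 7.69 TPM with shNC to 7.43 ± 0.634 TPM with shIFI16 (mean ± SD, n = 3 each). HMOX1 fell by 0.53 (log2, SE 0.0899, adjusted p = 3.0e-04), from 32.3 ± 2.34 to 22.1 ± 1.27 TPM. By the separately normalized tables, untested across them, HMOX1 with shNC lay near the control mean of 23.7 TPM. The radioresistant mean was 202 TPM, so most of that rise was not seen in the shNC libraries. Hairpin and table cannot be told apart there. GFAP rose by 3.56 (SE 0.116, adjusted p = 3.6e-12), from 1.73 ± 0.344 to 31.1 ± 1.67 TPM.

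Among the largest rises was MAGEA12, a cancer-testis antigen with close paralogs on the X chromosome, by 3.29 from 1.03 ± 0.255 to 18.7 ± 1.76 TPM. HEPH rose by 3.19 from 0.445 ± 0.0851 to 12.2 ± 0.692 TPM. The neuroendocrine secretory granule gene SCG2 rose by 2.91 from 18.1 ± 0.526 to 142 ± 7.14 TPM, and the neuronal adaptor gene BEX1 rose by 2.80. Keratin 8 (KRT8), an epithelial filament protein, rose by 2.79 from 12.3 ± 0.680 to 91.1 ± 2.60 TPM, and EHF, an epithelial transcription factor, rose by 2.43. The long non-coding RNA LINC01234 rose by 2.82, the protease-like gene PRSS35 by 2.72 and the membrane protein gene SUSD2 by 2.43. Adjusted p was at most 1.7e-05 (BEX1) over these rises.

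The falls beside IFI16 were led by NCEH1, a neutral cholesterol ester hydrolase, which fell by 2.55 from 110 ± 6.75 to 17.9 ± 1.36 TPM. GPNMB, a membrane glycoprotein of lysosomes and melanosomes, fell by 2.32 from 49.2 ± 1.2 to 9.03 ± 0.150 TPM. The pleckstrin homology protein gene PLEKHA6 (-2.24), BATF (-2.07), an AP-1 family transcription factor, and the membrane protein genes EVI2A (-2.02) and TMEM71 (-1.95) fell too. CD82, a tetraspanin, fell by 1.95 from 32.8 ± 2.83 to 7.76 ± 1.22 TPM. The uncharacterized gene LOC100131289 averaged 4.32 ± 0.693 TPM with shNC and was listed at 0 in all 3 shIFI16 libraries. Adjusted p was at most 2.0e-07 (BATF) over these. The long non-coding RNA LINC01605 fell by 2.53, but its adjusted p was 0.032 and lay above 0.05 in 6 of the 15 alternatives. These were the fit with a replicate block (0.091) and those without shNC replicate 1 (0.10), 2 (0.098) or 3 (0.10) or without shIFI16 replicate 1 (0.071) or 2 (0.11), within a range of 6.65e-12 to 0.11.

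Of 22 lists tested, 11 passed camera's test with the preset correlation, 7 downward and 4 upward. Interferon-stimulated genes fell in 25 and rose in 5 of 40 cases, and in 26 and 7 adjusted over the list alone (median -0.44, adjusted p = 1.1e-06; adjusted p = 0.20 with an estimated correlation). The chemokine genes CXCL11 (-1.38) and CXCL10 (-0.87), OASL (-1.08) and IFIT2 (-1.05), which binds viral RNA, fell. Against this direction, IFITM1 rose by 1.24 from 127 ± 9.10 to 301 ± 21.0 TPM. MX1 rose by 1.25, but only from 1.03 ± 0.361 to 3.78 ± 0.478 TPM. Antigen-presentation genes fell in 13 and rose in 1 of 18 cases, the same numbers as adjusted over the list alone (median -0.58, adjusted p = 1.1e-06; adjusted p = 0.20 with an estimated correlation), with HLA-B at -1.10 and B2M at -0.71. Nucleic-acid-sensing genes fell in 7 and rose in 0 of 16 cases, also adjusted over the list alone (adjusted p = 8.4e-04; adjusted p = 0.33 with an estimated correlation). IFI16, whose fall the hairpin set, is 1 of those 7. Without it 6 of 15 fell and 0 rose (median -0.18, adjusted p = 0.0055; adjusted p = 0.45 with an estimated correlation), DDX58 (-0.80) and IFIH1 (-0.62) among them. The median of the whole list was -0.19, and -0.30 without shIFI16 replicate 1.

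NF-kB targets fell in 14 and rose in 4 of 21 cases, also adjusted over the list alone (median -0.67, adjusted p = 2.9e-05; adjusted p = 0.16 with an estimated correlation). The cytokine gene IL6 (-1.44), the NF-kB inhibitor TNFAIP3 (-1.36), CXCL8 (-1.35) and the mitochondrial superoxide dismutase SOD2 (-1.06) fell. Secreted senescence factors fell in 16 and rose in 5 of 31 cases, and in 17 and 6 adjusted over the list alone (median -0.40, adjusted p = 0.0017; adjusted p = 0.20 with an estimated correlation). The median was -0.17, -0.24 and -0.21 without shNC replicate 1, 2 and 3. Osteopontin (SPP1) fell by 1.79 from 403 ± 21.9 to 116 ± 2.26 TPM, the stress cytokine GDF15 fell by 1.60, and IGFBP4 rose by 1.89 and STC1 by 1.15. Immediate early genes fell in 7 and rose in 2 of 15 cases, also adjusted over the list alone (median -0.30, adjusted p = 0.0030; adjusted p = 0.33 with an estimated correlation), with IER2 at -0.69 and JUN at -0.68, and EGR1 rose by 0.54. Mesenchymal glioblastoma genes fell in 10 and rose in 4 of 27 cases, also adjusted over the list alone (median -0.09, adjusted p = 0.037; adjusted p = 0.45 with an estimated correlation). The galectin LGALS1 (-0.85) and the AP-1 gene FOSL1 (-0.73) fell, and CHI3L1 and CEBPD rose by 1.59 and 1.01. That list did not pass with median-ratio scaling (adjusted p = 0.13), quantile normalization (0.080) or without shIFI16 replicate 3 (0.058, median -0.06), within a range of 0.027 to 0.13.

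Upward calls by camera were made for 4 lists. Hypoxia and glycolysis genes rose in 14 and fell in 2 of 24 cases, and in 17 and 2 adjusted over the list alone (median 0.25, adjusted p = 3.7e-04; adjusted p = 0.45 with an estimated correlation); EGLN3 rose by 1.16, NDRG1 by 0.84 and the mitophagy receptor BNIP3 by 0.74. NRF2 targets rose in 12 and fell in 2 of 27 cases, also adjusted over the list alone (median 0.21, adjusted p = 0.0030; adjusted p = 0.45 with an estimated correlation). The risen members included the pentose phosphate gene TKT (0.53), and the 2 that fell were AKR1C1 (-0.92) and HMOX1. Cholesterol synthesis genes rose in 10 and fell in 1 of 23 cases, and in 12 and 1 adjusted over the list alone (median 0.22, adjusted p = 0.021; adjusted p = 0.58 with an estimated correlation), with SQLE up by 0.87; without shIFI16 replicate 1 the median was 0.12. Ribosomal protein genes rose in 21 and fell in 2 of 76 cases, also adjusted over the list alone (median 0.09, adjusted p = 0.0030; adjusted p = 0.80 with an estimated correlation), RPL8 by 0.37. The ribosomal call ended with median-ratio scaling (adjusted p = 0.064), without shNC replicate 1 (0.17) and without shIFI16 replicate 3 (0.072), within a range of 2.0e-05 to 0.17, and by fry it was not made (adjusted p = 0.20).

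Ferroptosis lists did not pass after knockdown. Of 27 suppressors 5 rose and 5 fell, with 6 and 5 adjusted over the list alone (median 0.06, mean -0.0015, adjusted p = 0.68); the tetrahydrobiopterin enzyme gene GCH1 fell by 1.00, GPX4 fell by 0.31 (adjusted p = 0.0010), and the ferritin light chain gene FTL rose by 0.36. Of 24 drivers 2 rose and 6 fell, with 2 and 7 adjusted over the list alone (adjusted p = 0.20), including SAT1 (-0.98), ACSL4 (-0.34) and the transferrin receptor gene TFRC (-0.33). Heme and iron genes rose in 4 and fell in 10 of 28 cases, also adjusted over the list alone (adjusted p = 0.13), with HEPH up by 3.19 and the biliverdin reductase gene BLVRA down (-0.55). Cell-cycle inhibitors rose in 1 and fell in 4 of 10 cases, also adjusted over the list alone (adjusted p = 0.20): CDKN1A (-0.85) and CDKN2D (-1.02) fell, and BTG2 rose by 2.23. p53 targets rose in 6 and fell in 9 of 29 cases, with 6 and 10 adjusted over the list alone (adjusted p = 0.20). Proliferation genes rose in 12 and fell in 18 of 47 cases, with 13 and 20 adjusted over the list alone (adjusted p = 0.23), CCNE2 up by 0.71 and CENPA down (-0.52). DNA break repair genes rose in 9 and fell in 3 of 37 cases, with 10 and 3 adjusted over the list alone (adjusted p = 0.32), and proneural and stem genes in 2 and 4 of 7, also adjusted over the list alone (median -0.17, mean 0.09, adjusted p = 0.65), where PDGFRA rose by 1.79. Extracellular matrix genes rose in 9 and fell in 11 of 29 cases, with 10 and 12 adjusted over the list alone (median 0.01, mean -0.02, median -0.0043 with median-ratio scaling, adjusted p = 0.64), including the proteoglycan gene BGN (2.32) and fibronectin FN1 (-1.13). Stress response genes rose in 7 and fell in 8 of 25 cases, with 8 and 9 adjusted over the list alone (median -0.05, mean 0.01, adjusted p = 0.68), and replication histones in 2 and 1 of 21, also adjusted over the list alone (adjusted p = 0.65).

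Of 4 tested astrocyte markers GFAP and FABP7 (0.45) rose and 0 fell, too few for a list test. Among markers of other cell types the macrophage gene CD68 fell by 1.25, CDH5 rose by 1.28 while the endothelial gene ROBO4 fell by 1.23, and NEFL rose by 0.26 while SYT1 fell by 0.72. In sum 1 immune, 3 endothelial, 2 epithelial, 4 neuron and 1 oligodendrocyte marker were tested; the epithelial marker CLDN4 fell by 0.47 and the oligodendrocyte marker CNP rose by 0.46. Without shNC replicate 1 CLDN4 did not pass (adjusted p = 0.053, range 0.0035 to 0.053 over the alternatives). The counts adjusted over the list alone were the same for all 6 marker lists.

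By limma with Benjamini-Hochberg adjustment 4140 of 12567 tested genes changed, 2088 up and 2052 down, 5324 had an unadjusted p under 0.05, and 160 raised and 149 lowered genes changed at least 2-fold. The 160 became 84, 91 and 100 without shIFI16 replicate 1, 2 and 3, and 169, 154 and 155 without shNC replicate 1, 2 and 3. Genes at 1 TPM or more only in shIFI16 cells went untested when a shIFI16 library was left out. The filter therefore set part of that drop. A pseudocount of 0.1 TPM gave 252 raised and 234 lowered. The groups did not overlap in 5626 genes (44.8%), where chance gives 10%. Leaving out shIFI16 replicate 2 gave 1318 raised genes in place of 2088.

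Changes after IFI16 knockdown went both against and along those of radioresistant cells. The interferon-inducible HLA-B, OASL and IFIT2, the cytokine receptor gene IL4R and EVI2A were raised in radioresistant cells. With shIFI16 they were lower than with shNC, with log2 changes of -1.10, -1.08, -1.05, -1.60 and -2.02. GFAP, GPM6B, PRSS35, SCUBE3 and ZNF423 were lowered in radioresistant cells and higher with shIFI16 than with shNC, by 3.56, 1.79, 2.72, 2.29 and 2.18. For some of these genes the shNC libraries lay beyond the radioresistant levels of the other table, which was normalized separately, so levels were not tested across the tables. GFAP averaged 80.6 TPM in radioresistant, 1.73 in shNC and 31.1 in shIFI16 cells, OASL 71.3, 507 and 239 TPM, and IFIT2 41.1, 248 and 120 TPM. With shIFI16 GFAP was thus still below, and OASL and IFIT2 still above, the radioresistant level, whereas GPM6B averaged 7.70, 3.99 and 16.3 TPM. HLA-B, at 818, 69.3 and 31.8 TPM, was already lower with shNC, and only 3 of 35 interferon genes raised at least 2-fold had an shNC mean at or above the radioresistant one. Among 12359 genes tested in both comparisons, which shared no library, 546 (IFI16 itself among them) were raised in radioresistant cells and lowered by shIFI16, where independent lists give 331 (odds ratio 2.22, Fisher's exact test across genes, two-sided p = 1.0e-40). A further 595 were lowered and then raised, against 544 (odds ratio 1.16, exact p = 0.0052), 385 were raised in both against 342 (odds ratio 1.19, p = 0.0058) and 491 were lowered in both against 527 (odds ratio 0.893, p = 0.046). Exact tests count each gene as independent, so the p-values of all these overlaps do not measure the spread between libraries. Genes moved together, with estimated correlations of 0.0887 and 0.210 in the sets raised and lowered at least 2-fold. With no fold limit the first overlap passed in all 21 alternatives, with odds ratios of 1.59 to 2.79, and each other overlap missed the threshold in some. Lowered then raised genes did not pass without control replicate 3 (exact p = 0.11) or shIFI16 replicate 1 (0.053), within a range of 2.1e-14 to 0.11, and numbered 392 without shIFI16 replicate 2. Genes raised in both did not pass with quantile normalization (exact p = 0.41), a replicate block (0.66) or without control replicate 3 (0.59), radioresistant replicate 2 (0.23) or 3 (0.33) or shIFI16 replicate 3 (0.64), within a range of 1.2e-12 to 0.66. Their odds ratio turned to 0.974 with the block and 0.969 without shIFI16 replicate 3, and they numbered 253 without radioresistant replicate 3 and 246 without shIFI16 replicate 2. Genes lowered in both did not pass in 13 of 21 alternatives (exact p 3.6e-07 to 1.0, odds ratio 0.765 to 1.09). Among these were the fits without control replicate 1 (0.20) or 2 (1.0), radioresistant replicate 1 (0.17) or 3 (0.77) and shIFI16 replicate 1 (0.71). Of the 144 genes changed at least 2-fold in both, 111 (77.1%) went in opposite directions. At this limit 57 were raised then lowered, against 5.79 from independent lists (odds ratio 18.6, exact p = 9.4e-43), and 54 lowered then raised, against 8.28 (odds ratio 10.5, exact p = 2.2e-30). Both passed in all 21 alternatives, with odds ratios of 14.5 to 19.8 and 7.30 to 15.5, though the 54 became 34 without shIFI16 replicate 1. Raised in both were 28 against 6.60 (odds ratio 5.22, exact p = 6.4e-11), which missed the threshold only without shIFI16 replicate 1 (exact p = 0.095, range 1.3e-18 to 0.095 over the 21). These 28 became 16 without radioresistant replicate 1 or 2 and 7, 9 and 11 without shIFI16 replicate 1, 2 and 3. Genes at 1 TPM or more only in the group that lost a library, such as HEPH in shIFI16 cells, went untested in those fits. The filter thus set part of these drops, of the missed threshold and of the drop from 54 to 34, a part not measured. With pseudocounts of 0.1 and 0.5 TPM they became 50 and 40. Lowered in both were 5 against 7.26 (odds ratio 0.673, exact p = 0.56), or 3 without control replicate 3. With those pseudocounts they were 16 (odds ratio 1.19) and 13 (odds ratio 1.28). This overlap did not pass in any of the 21. Raised in both were IFITM1, IFITM2, MX1, HEPH and CHI3L1 among others, chosen after their values were seen. Fold changes had a Pearson r of -0.168 and a Spearman rho of -0.059 across the 12359 genes, which are not independent replicates.

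As a set, the 555 genes raised at least 2-fold in radioresistant cells lay lower than other genes after knockdown (median -0.17, camera adjusted p = 4.5e-06 over the 2 sets; adjusted p = 0.32 with an estimated correlation), with 237 lowered and 99 raised. Leaving out the interferon and antigen-presentation lists left 509 genes and an adjusted p = 1.0e-04 (adjusted p = 0.45 with an estimated correlation). Interferon-related genes outside those lists, such as ISG20, IFNB1 and LY6E, stayed among the 509. The removal thus cannot show a shift apart from interferon. The 696 genes lowered at least 2-fold lay higher (median 0.09, adjusted p = 0.0063; adjusted p = 0.56 with an estimated correlation), with 204 raised and 110 lowered. That median was 0.024 without shIFI16 replicate 1 and 0.14 without shIFI16 replicate 3. With no fold limit on them the raised and lowered sets did not pass (adjusted p = 0.11 and adjusted p = 0.51). Over the alternatives, the estimated correlation among them, unadjusted p-values ranged from 5.5e-10 to 0.16 and from 0.0015 to 0.56.

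**Figure D3:**
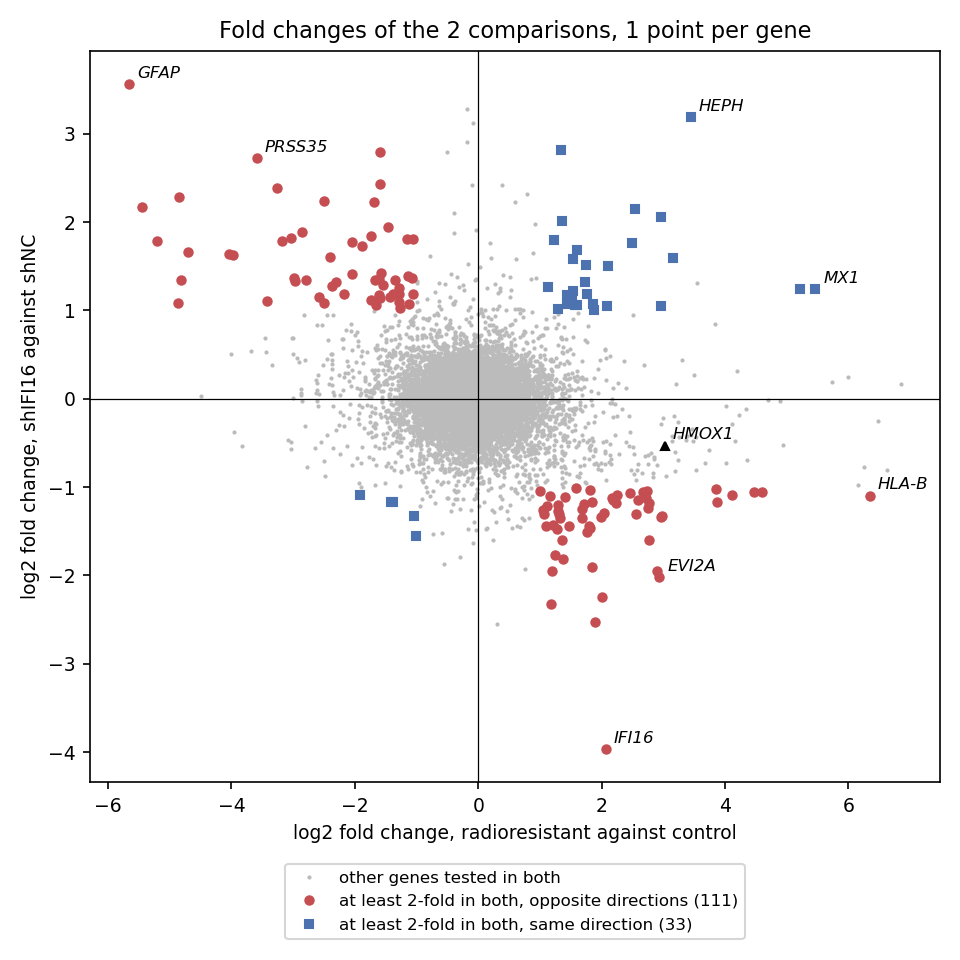
Log2 fold change of each of 12359 genes in radioresistant against control cells (horizontal axis) and in shIFI16 against shNC cells (vertical axis). Red circles are the 111 genes that changed at least 2-fold in both comparisons in opposite directions, blue squares the 28 raised in both and the 5 lowered in both, and the triangle is HMOX1 at 3.02 and -0.53.

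Open chromatin was described by 1 ATAC-seq library per condition, so differences between the libraries have no replicate check. The control list held 2454 summits and the radioresistant list 12877, 5.25 times as many, with median scores (the authors' -log10 q) of 3.57 and 4.08. At a score of at least 10 the lists held 56 and 668 summits, 11.9 times as many. Of the control summits 1476 (60.1%, 95% Clopper-Pearson interval 58.2 to 62.1) lay within 250 bp of a radioresistant summit, and 11.5% of the radioresistant summits (10.9 to 12) lay as near a control summit. IFI16 had a summit in the radioresistant list at position 158999953 of chromosome 1 (score 6.80), 23 bp outside the annotated gene, and none in the control list within 1 kb of the gene. HMOX1 had no summit within 1 kb of either gene end in either list. NCEH1 had a summit 181 bp outside the gene in the control list (score 7.90) and 132 bp outside in the radioresistant list (score 17.8), PRSS35 had one in each list and CD82 one in the radioresistant list. Of the 43 named genes with coordinates 30 had no summit in the gene or within 1 kb, LY6E, RSAD2, HLA-B, MX1, GFAP and HEPH among them. In the radioresistant list a summit lay within 1 kb of a gene end for 28.8% (26.9 to 30.8) of 2064 raised genes, 34.8% (33.1 to 36.4) of 3263 lowered genes and 36.5% (35.3 to 37.6) of 6742 genes not past the threshold. The order of lowered and other genes turned when summits anywhere in the gene or within 1 kb were counted (53.6% against 48.9%) and at a score of at least 10 (2.45% against 1.96%). The control list gave 6.20%, 5.52% and 6.57% within 1 kb of a gene end. Intervals cover counting error only, and a gene without a listed summit is not shown to be closed, since the depth of the libraries is unknown.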

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

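The settings of pseudocount, filter, scaling, small RNA, plain limma and the 2-fold test, of the sensing list without IFI16, and of summits on the main chromosomes only, within genes or near genes changed at least 2-fold, were chosen after seeing the data. Of the values of the comparisons under alternatives, 244 kept their side of the threshold or, with no test, stayed within 1.5 times (counts) or the 95% interval (shares), 29 moved further and 4 lost their call; for single genes and lists 3362 were the same, 21 lost and 9 gained a call, and 1 reversed. IFI16 ranged from 1.90 to 2.18 in radioresistant and from -4.12 to -3.90 in shIFI16 cells, and HMOX1 from 2.83 to 3.14 and from -0.58 to -0.48, past the threshold in the 15 alternatives run for each, which did not include the 2-fold test. Testing against a 2-fold limit gave 488 genes (5762 without) and 77 (4140 without), a stricter question by construction, and a pseudocount of 0.1 TPM gave 252 raised and 234 lowered genes at least 2-fold changed in shIFI16 cells (160 and 149 with 1 TPM). In radioresistant and shIFI16 cells 14 and 11 lists passed, and 17 and 10 did by fry, a different question. With an estimated correlation 0 and 0 passed, but that form also raised p where the correlation was estimated under 0.01. With an estimated correlation the medians of the raised and lowered sets, -0.17 and 0.09, were no longer past the threshold; with no fold limit the medians were -0.014 and 0.029, also not past it. A fold limit of 2 in both comparisons left 111 genes in opposite directions. With single libraries left out, lowered genes in radioresistant cells ranged from 2237 to 4395, raised genes in shIFI16 cells from 1318 to 2310, and SLC7A11 in radioresistant cells from -0.018 (without control replicate 3, the 1 reversal) to 0.22. Control summits shared were 36.1% at 100 bp, 73.7% at 500 bp, 75.8% at 1000 bp, 75% at a score of at least 10 and 29.7% with equal numbers of top summits. Genes near a radioresistant summit, for raised, lowered and other genes, were 24.9%, 29.4% and 32.3% at 500 bp; 38.1%, 44.0% and 45.1% at 5 kb; 1.89%, 2.45% and 1.96% at a score of at least 10; 7.12%, 8.58% and 9.0% with equal numbers; and 44.0%, 53.6% and 48.9% within the gene or 1 kb of it. Among genes changed at least 2-fold they were 18.1% of raised and 26.5% of lowered genes. The filter on left-out libraries, which dropped genes high only in the reduced group, lowered counts of genes at least 2-fold changed by construction. Apart from that, the 2-fold limits and the distances, the cause was not tested. Replicate numbers did not pair the libraries of the first comparison. There the correlations of same-numbered deviations were -0.377, 0.245 and 0.081, with the own number the best partner for 1 of the 3 numbers. A replicate block gave 5572 changed genes (5762 without). In the second the correlations were small but positive (0.215, 0.088 and 0.028), with the own number best for 2 of the 3. The block gave 5610 changed genes there (4140 without), so an effect shared by replicate number stays open in the knockdown. Planned settings that need counts (other size factors, library totals alone, count filters, a second count tool, voom and the count-based fold test) were not run. Depth is unknown, so what it limits could not be stated.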

Other observations

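All families and tests in this part except the splits for the sets and for opposite genes were chosen after the results were seen. Of the beta protocadherins, cell-surface adhesion molecules of neural cells, 12 of 12 tested fell in radioresistant cells (median -1.19, and -1.10 and -1.08 with median-ratio scaling and quantile normalization), with log2 changes of -2.63 for PCDHB7 and -2.10 for PCDHB10. After IFI16 knockdown the median of 6 tested members was -0.03 (-0.04 and -0.05 with those scalings). Of 10 SOX transcription factor genes 6 fell and 1 rose in radioresistant cells, with log2 changes of -2.58 for SOX21 and -1.81 for SOX4, and 2 rose with either other scaling; after knockdown 3 rose, or 2 with median-ratio scaling. All 4 tested guanylate-binding protein genes, interferon-inducible GTPases, rose in radioresistant cells and fell after knockdown, with TPM as deposited, median-ratio scaling and quantile normalization; GBP1 had log2 changes of 3.36 and -0.46 and GBP3 of 1.94 and -0.75. All 4 tested APOL genes rose in radioresistant cells, APOL1 by 4.89 and APOL3 by 4.02, and 1 of 4 fell after knockdown. IFNB1, which encodes interferon beta, had a log2 change of -1.30 after knockdown (limma adjusted p = 4.7e-08), from 32.4 ± 2.21 to 12.6 ± 0.828 TPM. In radioresistant cells it rose by 2.03 (limma adjusted p = 5.2e-05), from 0.678, 0 and 0 TPM in the control libraries to 3.90 ± 0.719 TPM, so by the separately normalized tables, untested across them, IFNB1 with shIFI16 still lay above the radioresistant level. Under 1 TPM in all control libraries, IFNB1 passed the filter through the radioresistant ones, which set the direction of that rise.

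Control replicate 3 stood apart from control replicates 1 and 2, with FTH1 at 1703 against 335 and 541 TPM and RPL41 at 3249 against 946 and 1114 TPM. RNA of radioresistant cells in that library would raise its interferon genes, but their median difference was -0.395 (quartiles -0.595 and -0.174), with 35 of 39 lower, which argues against such RNA as the cause. Other values went the other way: across genes, the library had Pearson's r of 0.940, 0.933 and 0.931 with the radioresistant libraries (controls 1 and 2 0.918 to 0.932), and RPL41 lay at 2816 to 3316 TPM in those. A trend with the genomic span of genes, introns included, had a Spearman rho of -0.395 in that library (others -0.338 to 0.371). After its removal the spread was still 1.76 times that between the other controls, so a trend with span is unlikely to be the whole cause. Transcript length, GC content and biological explanations were not tested, and a library or culture difference stays open.

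Interferon genes in shNC cells lay far from the radioresistant libraries of the other table, although both carry radioresistant cells by the labels. Over the 35 interferon genes raised at least 2-fold in radioresistant cells, the log2 difference had an interquartile range of 2.29, which argues against 1 scaling factor between the separately normalized tables. Of the list members left out, CXCL10 and CXCL11 lay at 0.941 and 0.265 TPM in radioresistant and at 90.7 and 38.7 TPM in shNC libraries. GBP2, PARP9, PARP14 and STAT2, also left out, lay lower in the shNC libraries. Interferon genes sat at a median share of 0.0586 of the way from control to radioresistant levels and lowered genes at 0.976, a gap of 0.917 that argues against control cells mixed in. The hypothesis that genes IRF3 can drive directly were kept and genes that need the interferon-receptor factor ISGF3 were lost may not describe the first class: its genes not seen before lay above radioresistant levels (median 2.72) and the others below (median -2.80), a difference of 5.53 given as a description across tables, but only CCL5 and HERC5 were direct genes, too few to tell. Over all 13 and 23 class genes, which include those that prompted the split, the medians were 2.58 and -3.42, and the hairpin and the table cannot be told apart, since shNC libraries stand in the second table only.

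In shIFI16 cells the interferon genes did not move together: of the direct class 0 rose and 12 fell of 13, and of the other class 5 rose and 9 fell of 22. The hypothesis that direct genes were lowered more might rest on genes already seen, since the unseen ones gave a difference of -0.23 (CCL5 and HERC5 against 16, exact permutation p = 0.33, two-sided), too few to tell. Over all class genes, which include those that prompted the split, the difference was -0.99, and no technical explanation was tested.

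Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. The real splits gave 5762 and 4140 genes, each the 1 split with as many, against at most 2 in other splits, and 14 and 11 lists against at most 10. Every other split mixes the groups and so puts a difference between them into its own spread. Few gene calls in those splits were therefore near certain and say little on chance. For the raised set 2 splits had a p as small, the real one (2.3e-06) and that of shNC 1, shNC 3 and shIFI16 3 against the rest (1.3e-06). For the lowered set the real p was 0.0063 and the smallest other 0.016, and opposite genes numbered 1141 against at most 0; as the other splits call at most 2 genes, that count was bound to lie near 0 and says nothing on direction.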
